A study of Drosophila melanogaster with 3 samples.

How the data were processed

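The series holds chromatin immunoprecipitation followed by sequencing (ChIP-seq) from whole Drosophila melanogaster embryos aged 0 to 24 h. The flies carried a transgene for so-eGFP, a fusion of the homeodomain protein Sine oculis (So) with a green fluorescent protein, and the precipitation used an antibody against GFP. Per the labels, chromatin was sonicated to fragments of 200 to 800 bp and the 3 samples are biological replicates 1, 2 and 3. The 3 samples form 1 group, so no comparison between groups was possible, and no control or untagged peak list was used here.

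Processing before deposit is known from the labels and the deposited text notes. These name the dm6 genome, alignments of each sample and a control alignment, and lists of peaks thresholded or ranked by the irreproducible discovery rate (IDR). The peak caller, its version, the aligner and the filters are not given in the sources used here. Each replicate had its own thresholded list and a longer ranked list of weaker peaks, so peaks were called per sample as well as on the series. Of the 4 thresholded lists of the whole series, the one named conservative was taken as the main peak set. The notes do not say which replicates each whole-series list set against each other. The 4 ranked lists of the whole series were not used, because each holds 8 columns of per-sample values that nothing assigns to a sample, 32 columns in total.

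The lists carry 4 kinds of value. The deposited score is a scaled IDR with a cap of 1000, and its lowest value in every thresholded list was 830. The deposited signal value is the peak caller's strength of the peak, on a scale that is not stated, and it was used to rank peaks within a list, for rank correlation and for medians compared within 1 list. The deposited −log10 q-value entered no test, and the −log10 of the global IDR, deposited in the replicates' ranked lists, was used to find the threshold. The score followed from the global IDR, to within 1 unit, in 100% of ranked peaks of each replicate, and the highest global IDR among thresholded peaks was 0.01. Of ranked peaks at or under that IDR, 57, 127 and 94 were not in the thresholded lists of replicates 1, 2 and 3, for a reason not given in the sources used here. The summit is deposited as a distance from the start of the peak. No list gives read counts, so the sequencing depth is unknown, and every interval below covers counting error over peaks only.

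Coordinates are dm6, counted from 1. Genes came from Ensembl release 115 and sequence from the Release 6 assembly, whose chromosome lengths hold the end of every peak. Peaks on the 6 assembled arms X, 2L, 2R, 3L, 3R and 4 were analysed. Peaks were called shared when they overlapped by 1 bp or more. The planned test of the number in all 3 replicate lists against 100 random placements of those lists was run but supports no statement here, because the conservative list had been selected from the same samples. A promoter summit lay within 500 bp of a start site of a protein-coding gene. The share of such summits was set against 10000 draws of random positions on the same arms (two-sided binomial simulation test). The draws were binomial counts per arm, from the share of its bases within 500 bp of a start site. They treat summits as independent, although some peaks overlap. The TGATAC core of the homeodomain family that So belongs to was searched on both strands within 100 bp of each summit, against windows of the same size 1000 bp to each side, with Fisher's exact test. CAGGTAG, GAGAGAG, TATCGATA and GGTCACACT, known for Zelda, GAGA factor, DREF and promoter Motif 1, were searched the same way, with Benjamini-Hochberg adjustment over the 5 words, and all hexamers found in at least 20 peaks were ranked. The share of peaks on the X was set against the X share of sequence length with an exact binomial test. Signal was compared between replicates by Spearman's rho across peaks, which are not independent replicates.

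A gene had a peak when a summit lay inside it or within 2 kb of it. Each of 21 gene lists was set against 10000 random lists matched in 20 bins on the length of the gene with its 2 kb on each side (two-sided permutation test, Benjamini-Hochberg adjustment over the 21 lists, threshold 0.05). The transfer RNA and histone lists used all genes as background and the others protein-coding genes. In 2 lists 1 member each was not matched to the annotation and is not analysed here. The genes named were so, the first 25 distinct genes nearest to the strongest conservative-list peaks found in all 3 replicate lists, and up to 4 members of each list with the strongest peaks, with up to 2 members without a peak. Other names were chosen after their values were seen and are marked so. Shares carry Wilson 95% intervals, and means over replicates their SD.

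The tests were checked on simulated data. With 4340 random positions, 4, 6, 6 and 7 of 100 runs passed the threshold for the promoter, core, X and strength tests, and a core planted in 3% of peaks was found in 100 of 100 runs. With peaks placed by gene length alone, 1 of 760 gene list tests passed, and a ribosomal protein list with a peak added to 40% of members was called in 40 of 40 runs. These simulations follow what the tests assume. They check the calculation and do not cover uneven base composition, overlapping peaks or genes that share a peak. The main peak set, the words, the gene lists, the tests, the rule for named genes and all but 2 kinds of alternative were chosen before the data were examined. No deposited list could be matched to a pair of replicates, so the alternative that sets a replicate aside kept the conservative-list peaks that overlap a thresholded peak in both other replicates. The conservative list itself was still made from all 3 samples, so this is not a peak set called without that replicate. Other alternatives covered the peak list, the overlap, the windows, the background, the start sites and the assignment of peaks to genes. Work was done with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.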

Results

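Binding of so-eGFP was mapped in 3 biological replicates of whole embryos. Sine oculis is a homeodomain protein known for its part in eye development. Its gene, *so*, lies on chromosome 2R (7419350 to 7434872, plus strand). The replicates' own thresholded lists held 2354, 2840 and 2125 peaks, and the conservative list of the series held 4343, of which 4340 lay on the 6 arms. Sequencing depth is unknown for all 3 replicates. The signal values quoted are the authors' own and rank peaks within a list.

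Of the peaks found in every replicate list, the highest was in an intron of CG11050 (FBgn0031836) on chromosome 2L (6612430 to 6612916), with a signal value of 1941, and it ranked 1 in each replicate's own list. It was followed by peaks at the promoter of Ugalt (FBgn0024994), a UDP-galactose transporter gene (X, 2703703 to 2704061, signal value 1778), in an intron of HmgZ (FBgn0010228), a high-mobility-group gene (2R, 21703173 to 21703661, 1453), and at the promoter of CG14100 (FBgn0036889; 3L, 19590461 to 19590770, 1401). Chro, which encodes a chromodomain protein, held the next at its promoter, with a signal value of 1227. Trl, the gene for GAGA factor, had an intronic peak of 1188 (3L, 14759333 to 14759698). Of the Polycomb group genes, ph-p had a promoter peak of 1164 (X, 2137184 to 2137525). Psc had the nearest start site, 4215 bp away, to an intergenic peak of 949 (2R, 12985065 to 12985381).

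Among the first 25 genes taken from peaks in all 3 replicate lists, 17 had the summit at a promoter and 6 were on the X. The mitochondrial ribosomal protein genes mRpL41 and mRpS10 were among them, with signal values of 1145 and 1101 and summits 155 and 123 bp from a start site. So were PNPase, Gapdh2, Fkbp14, Tina-1, Tcs5, CG18549, CG7601 and CG1635, each with a promoter peak. CenG1A held a promoter peak ranked 6, and Tlk, CG32772 and px held peaks ranked 18, 17 and 24. CG13323 and CG4004 had the nearest start sites, 11913 and 5014 bp away, to intergenic peaks. The TGATAC core lay within 100 bp of 1 of these 25 summits, at the promoter of CG13390, and GAGAGAG lay at 2, those of Tlk and px.

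How far the replicates shared peaks was asked of all 4340 conservative-list peaks. A total of 1030 peaks (23.7%, 95% interval 22.5 to 25.02) overlapped a peak in all 3 replicate lists, 912 in 2 lists, 1173 in 1 list and 1225 (28.2%) in none. The conservative list was made from the same 3 samples, so these shares describe its peaks and do not test how far the replicates match. Replicate 2 held 2426 of the conservative-list peaks, replicate 3 held 1931 and replicate 1 held 1730. The median signal value was 244 for peaks in all 3 lists and 76.5 for peaks in none. Of the latter, 77.1% overlapped a peak in the ranked list of each replicate. Those ranked lists hold 102538, 101477 and 86213 peaks, and the share that would overlap them by chance was not computed. Across peaks, Spearman's rho of the signal between replicates was 0.551 for 1 and 2, 0.560 for 1 and 3 and 0.602 for 2 and 3 (mean 0.571 ± 0.0273, SD, n = 3 pairs), and over all ranked peaks the mean was 0.306. Requiring 50% reciprocal overlap left 674 peaks in all 3 lists, and counting the weaker ranked peaks raised the number to 3765.

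The *so* gene (FBgn0003460) itself held 13 conservative-list peaks in or within 2 kb of the gene, some of them overlapping each other. CG11145, a gene inside *so* (7427905 to 7428593) named after its values were seen, has the nearest start site for 5 of the 13, and *so* for 8, so which gene the former belong to is open. The strongest (7429273 to 7429637, signal value 771) ranked 39 of 4340, lay in an intron 10104 bp from the start site of *so*, was nearest to CG11145 and was in all 3 replicate lists, where it ranked 168, 24 and 29. Other intronic peaks at 7422911 to 7423597 (signal value 424.5) and 7427330 to 7427733 (249, nearest to CG11145) were also in all 3 lists. The promoter peak (7419194 to 7419597, 179) was in 1 list. TGATAC lay near the summit of 1 of the 13, an intronic peak at 7433081 to 7433484 found in 2 lists. The window reaching 50 kb to each side of *so* held 25 peaks, or 20 with overlapping peaks merged, against a median of 3 in 2000 random windows, and of 5 in the 489 of them with a like number of start sites, either way. The transgene carries *so* sequence too, and weaker ranked peaks in this window had a median signal value of 15.4, 16.9 and 14.2 in replicates 1, 2 and 3, against 9.60, 11.35 and 9.67 in random windows.

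**Figure D1:**
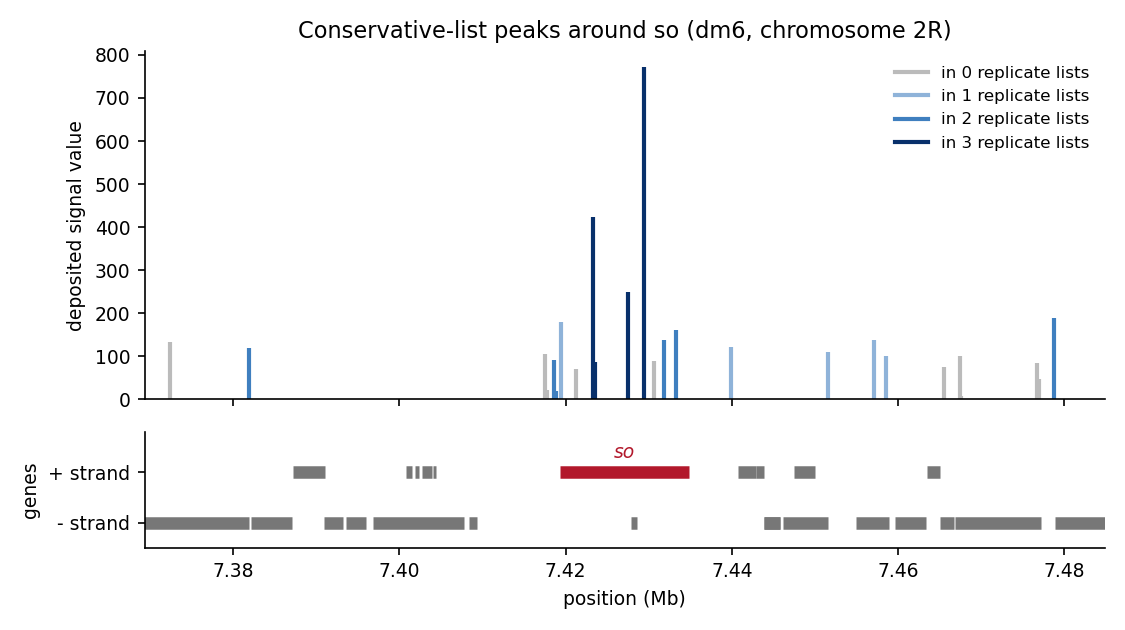
Conservative-list peaks around *so*. Lines mark peak summits on chromosome 2R by position in Mb, their height is the deposited signal value, and their shade gives the number of replicate lists that held the peak; bars below are protein-coding genes by strand, with *so* in red. The tallest of the 25 peaks, at 771, lies within *so*.

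Of the lists of eye development genes, 2 did not differ detectably from genes of their length and 1 lay below them. In the retinal determination network, which acts with So in the eye, 6 of 12 genes had a peak, against 46.3% of length-matched genes (permutation test, adjusted p = 1). Apart from *so*, these were Optix, dan, eyg, eya and tio, the last named after its value was seen, and their peaks ranked between 2677 and 3491 of 4340. The summit at dan lay outside the gene, 8979 bp from its own start site, at the promoter of another gene. No peak lay at dac or danr. Of the earlier reported So targets 5 of 9 had a peak, against 47.8% of matched genes (permutation test, adjusted p = 1). These were *so*, ct, stg, eya and Lim1, the last named after its value was seen, while ato and ey had none. In each of these lists *so* was the 1 gene with a peak in all 3 replicate lists. Genes of photoreceptor specification fell below matched genes, with 3 of 19 holding a peak, 15.8% against 45.0% (permutation test, adjusted p = 0.0392). These 3 were B-H1, ro and salr, whose strongest peaks ranked 2830, 2920 and 3821, and B-H2 and Kr had none. The strongest summit at ro lay outside the gene, 5397 bp from its own start site, at the promoter of another gene. That call was lost under 9 of 11 alternatives, among them conservative-list peaks found in the lists of replicates 2 and 3, 1 and 3, or 1 and 2 (permutation test, adjusted p = 0.246, 0.140 and 0.168). In the replicates' own lists the share was 5.26, 5.26 and 10.5% (7.02 ± 3.04%, SD, n = 3), below matched genes in 3 of 3, and passed the test in replicate 2.

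Cytoplasmic ribosomal protein genes stood furthest above matched genes among the 21 lists. Of 92 genes, 66 held a peak (71.7% against 21.4%, permutation p = 0.0002, the smallest 10000 draws can give, adjusted p = 0.0021), and the strongest summit of 52 of them lay within 500 bp of a start site of the gene. Among them were RpL3 (signal value 647), RpL32 (483) and RpL7 (436), and RpL10 and RpL10Aa had none. For RpL3 the strongest summit was 4767 bp from the gene's own start site, at the promoter of another gene. The share was 44.6, 54.3 and 57.6% in the lists of replicates 1, 2 and 3 (52.2 ± 6.79%, SD, n = 3), above matched genes in 3 of 3. It was the list that stayed past the threshold with peaks in all 3 replicate lists alone, where 1 of 21 lists passed (32 genes, 34.8% against 7.16%, permutation test, adjusted p = 0.0042).

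Of 21 gene lists, 6 passed the threshold, 4 above and 2 below matched genes, and 4086 of 13945 protein-coding genes (29.3%) held a peak. Transfer RNA genes had a peak in 81 of 290 cases (27.9% against 20.5%, permutation test, adjusted p = 0.0056), led by tRNA:Val-CAC-2-3 and tRNA:Val-CAC-2-4, which share 1 peak at the promoter of a protein-coding gene, 1814 and 2029 bp from their start sites. The test treated genes as independent, but the 81 genes rested on 58 peaks and 64 of them shared a peak with another, so its p may be too small. Against lists not matched on length the call was lost (permutation test, adjusted p = 0.972). Replicate 1 showed no such excess (8.62% against 8.78%, permutation test, adjusted p = 1), and with peaks in all 3 lists the share was 5.17% against 5.40%. The share was above matched genes in 2 of 3 replicates, and in conservative-list peaks found in the lists of replicates 2 and 3, 1 and 3, or 1 and 2 it was 11.0, 5.17 and 6.55%, none past the threshold and the second below matched genes. Muscle genes had peaks in 16 of 22 cases (72.7% against 39.5%, permutation test, adjusted p = 0.0084). Mef2, the myogenic regulator, held 8 peaks, the strongest of 712 and 1069 bp from its start site, and tin, a cardiac regulator, held 1 of 443, ahead of sls and Prm, while Act87E and Mlp60A had none. The strongest Mef2 summit lay outside the gene, at the promoter of another gene, and 1 of the 8 peaks was in all 3 replicate lists. The excess of muscle genes passed in replicate 2 (15 genes) and not in replicates 1 and 3 (8 and 10 genes), with shares above matched genes in 3 of 3. In the same 3 subsets of the conservative list the muscle list was not past the threshold (permutation test, adjusted p = 0.246, 0.953 and 0.782). Of the EGFR pathway 12 of 13 genes had a peak (92.3% against 49.99%, permutation test, adjusted p = 0.0151), led by aos, Mkp3, S and spi, with kek1 alone lacking one. By replicate the EGFR genes numbered 12, 10 and 9, above matched genes in 3 of 3, and they passed in replicate 1. The EGFR list was not past the threshold in these subsets either (permutation test, adjusted p = 0.109, 0.380 and 0.193). With peaks in all 3 lists, the muscle and EGFR lists held 4 and 5 genes and were not past the threshold (permutation test, adjusted p = 1 and 0.539). None of 111 replication-dependent histone genes held a peak, and none did in 3 of 3 replicates. They are near-identical repeats on chromosome 2L, such as His1:CG31617 and His1:CG33801, where reads often cannot be placed, and the test treated them as independent genes. Although this list is 1 of the 6 past the threshold, it is therefore not read as an absence of binding. Its call was lost in conservative-list peaks found in the lists of replicates 1 and 3 and in those found in all 3 lists (permutation test, adjusted p = 0.0630 and 0.176).

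**Figure D2:**
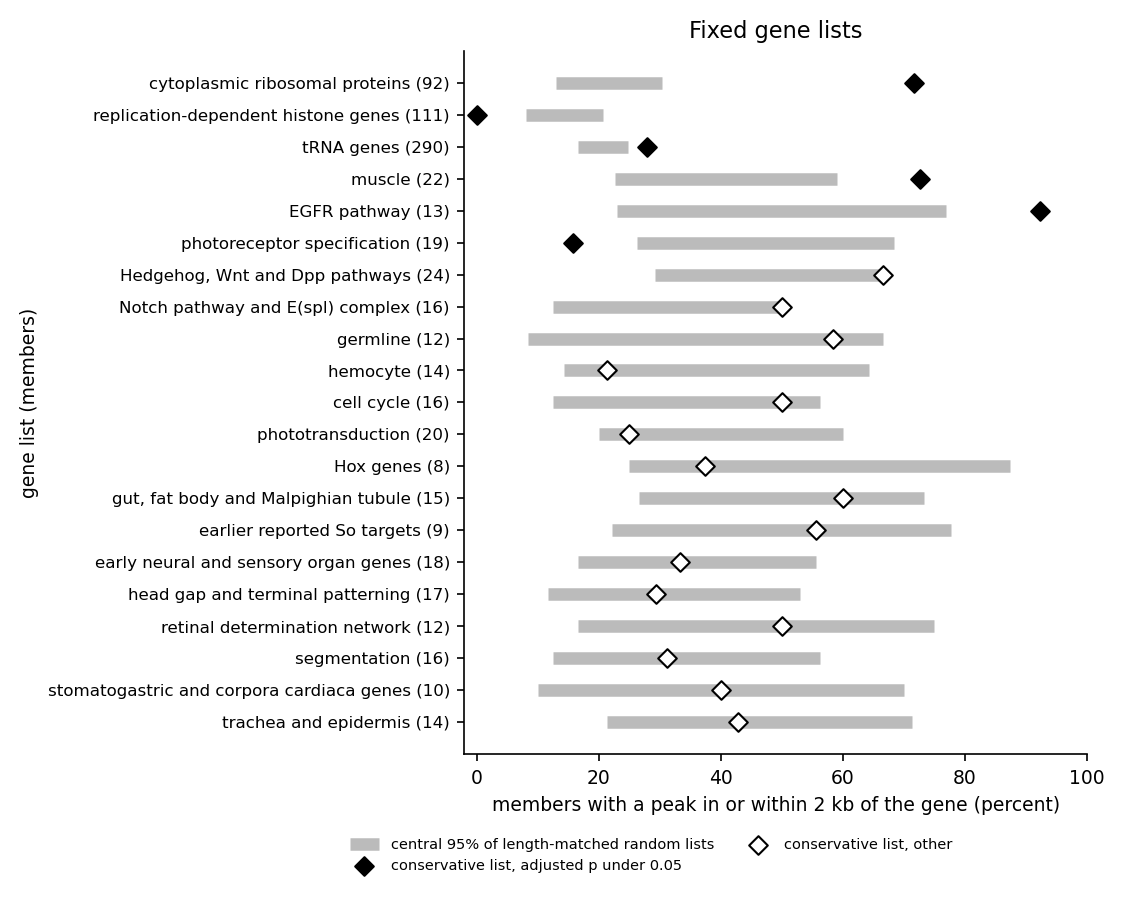
Share of each fixed gene list with a conservative-list peak, in percent of members. Diamonds are the observed shares, filled where the adjusted p was under 0.05, and grey bars are the central 95% of 10000 length-matched random lists; 66 of 92 cytoplasmic ribosomal protein genes held a peak.

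The other 15 lists did not pass the threshold (permutation test, adjusted p from 0.290 to 1), but 3 of them did under 1 alternative each. These were the Hedgehog, Wnt and Dpp genes against lists not matched on length (adjusted p = 0.00084, permutation test), cell cycle genes in the largest other list (75%, adjusted p = 0.0302) and head gap genes by the nearest start site (52.9%, adjusted p = 0.0203), the last turning from below to above matched genes. For the retinal network and the earlier targets the values are given above. The Hedgehog, Wnt and Dpp genes held peaks in 16 of 24 cases (66.7% against 48.05%, permutation test, adjusted p = 0.290), with gbb at a signal value of 739 and Med at 491. The summits at gbb and Med lay outside the gene, 1153 and 5105 bp from its own start site, at the promoter of another gene. The Notch pathway and its E(spl) complex had 8 of 16, led by mam, with 11 peaks, and E(spl)m8-HLH, whose summit lay at the promoter of another gene, 2283 bp away. Cell cycle genes had 8 of 16, led by fzr and CycB, and germline genes 7 of 12, led by bgcn and pum. The summit at fzr lay outside the gene, 10534 bp from its own start site, at the promoter of another gene. That at CycB was intergenic, 3329 bp from its start site. Among sensory and neural genes, 6 of 18 early neural genes had a peak, with elav at 574 and brat at 464. Of phototransduction genes 5 of 20 had one, with norpA at 554 and rdgC at 394, then rdgB, rdgA and Galphaq. Head gap genes had 5 of 17 (fkh, cnc, hb, D and gcm), segmentation genes 5 of 16 (hry, opa, sob, odd and inv) and Hox genes 3 of 8 (Abd-B, abd-A and Ubx). Of these, Galphaq and inv were named after their values were seen. Stomatogastric genes had 4 of 10 (amon, tin, fkh and sim), hemocyte genes 3 of 14 (ush, gcm and srp), gut and fat body genes 9 of 15, led by bowl, and tracheal and epidermal genes 6 of 14, led by trh.

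Summits of so-eGFP peaks lay at promoters, 1986 of 4340 (45.8%, 95% interval 44.3 to 47.2), against 11.5% of random positions. The ratio was 3.975 (two-sided binomial simulation test, p = 0.0002, the smallest 10000 draws can give). In the replicates' lists the share was 42.1, 50.5 and 46.1% (46.2 ± 4.21%, SD, n = 3). Introns held 37.2% of summits and 39.4% of the sequence, intergenic sequence 14.4% against 29.9%, and coding exons 0.876% against 13.3%. The median distance to a start site was 662 bp, and 819 summits (18.9%) lay more than 5 kb away.

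**Figure D3:**
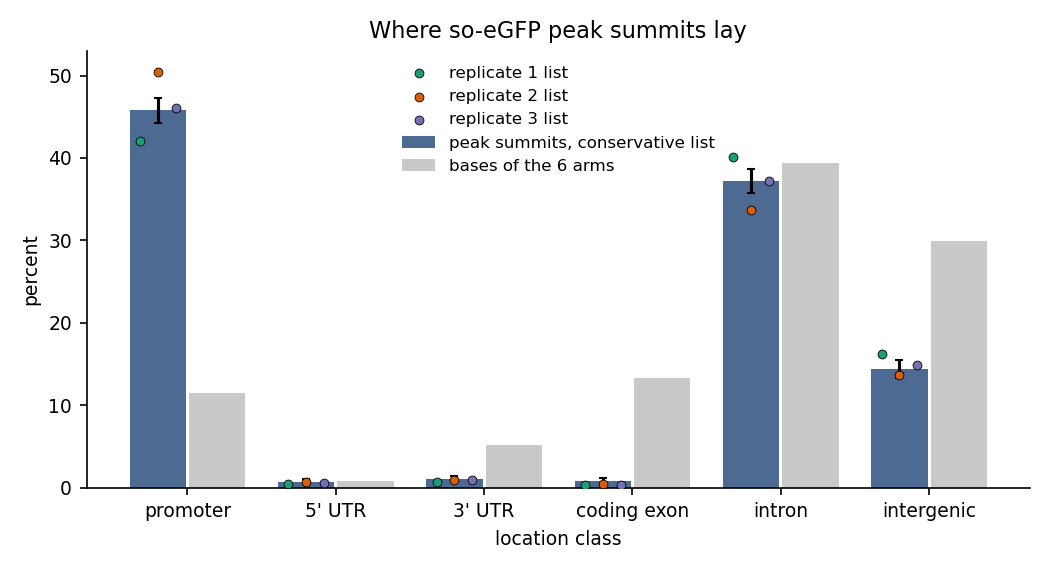
Location of summits by class, in percent. Blue bars give the conservative list with 95% intervals, grey bars the share of bases on the 6 arms, and points the lists of replicates 1, 2 and 3; promoters held 45.8% of summits and 11.5% of bases.

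The X chromosome carried 665 of 4340 conservative-list peaks (15.3%, 95% interval 14.3 to 16.4), below its 17.6% of sequence (exact binomial p = 8.47e-05). In replicate 1 it carried 21.1%, above that share (exact binomial p = 1.06e-05), and in replicates 2 and 3 it carried 15.7 and 15.96% (17.6 ± 3.05% over the 3 replicates, SD, n = 3). Fisher's exact tests between pairs of replicates gave adjusted p = 1.66e-06 for 1 and 2, 1.7e-05 for 1 and 3 and 0.8135 for 2 and 3. They treat peaks as independent, with 1 library per replicate and many peaks shared between them, so they support no statement about the replicates. Peaks in all 3 lists lay on the X in 20.5% of cases and peaks in none in 12.7%. Conservative-list peaks found in the lists of replicates 2 and 3 lay on the X in 16.9% of cases, not past the threshold, and those found in 1 and 3 or 1 and 2 in 21.2 and 20.4%, above the X share of sequence. Chromosome 4, which is largely heterochromatic, held 4 peaks, 3.005 per Mb against 28.3 on the X. Their nearest genes, named after the values were seen, were zfh2, for 2 of them, PlexA and lgs.

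The So-family core TGATAC lay near 252 of 4340 summits (5.81%), against 4.48% of flanking windows. The ratio was 1.30 (95% interval 1.11 to 1.51, Fisher's exact test, adjusted p = 0.00157). The replicates gave 1.37, 1.22 and 1.39 (1.33 ± 0.0937, SD, n = 3), above 1 in 3 of 3. The ratio was 1.60 for peaks in all 3 replicate lists, 1.55 for summits away from start sites and 1.03 for summits near them. Against dinucleotide-shuffled windows the direction turned, with a ratio of 0.783 (Fisher's exact p = 0.00285), and with windows reaching 200 bp to each side of the summit the ratio was 1.05 and the longer So consensus gave 1.06, neither past the threshold. Among 2080 hexamers the core ranked 121 by ratio. The leading hexamers were ACACTG (15.2% of peaks against 7.65%) and ACAGTG (15.8% against 8.11%). For peaks in all 3 lists they were AGTGTA (18.7% against 6.17%) and ACAGTG (23.1% against 8.40%).

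By ratio over the flanks, 3 of 4 words of promoter and chromatin factors exceeded the So-family core. The words differ in length and frequency, so this does not rank them by share of peaks. GGTCACACT lay at 1.22% of summits against 0.369% of flanks, and TGATAC at 5.81% against 4.48%. Unlike the core, these words were not split into summits near and away from start sites. The DREF word TATCGATA had a ratio of 3.55 (95% interval 2.54 to 4.96), and the replicates gave 4.55, 4.57 and 5.22 (4.78 ± 0.3835, SD, n = 3). Promoter Motif 1, GGTCACACT, had a ratio of 3.31 (2.14 to 5.13) and in the replicates 1.625, 3.89 and 3.29, the first of which did not pass the test. GAGAGAG, the word of GAGA factor, had a ratio of 2.06 (1.78 to 2.37) and in the replicates 0.843, 2.32 and 1.55. Its ratio in replicate 1 thus lay below 1 with an interval, 0.646 to 1.10, that includes it, and the median GC of the summit windows was 34.3, 40.3 and 38.8% in replicates 1, 2 and 3. CAGGTAG, the word of Zelda, was rarer than in the flanks (ratio 0.650, 0.451 to 0.935, Fisher's exact test, adjusted p = 0.0204), below 1 in 3 of 3 replicates (0.561, 0.838 and 0.906) and not past the threshold in replicates 2 and 3.

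**Figure D4:**
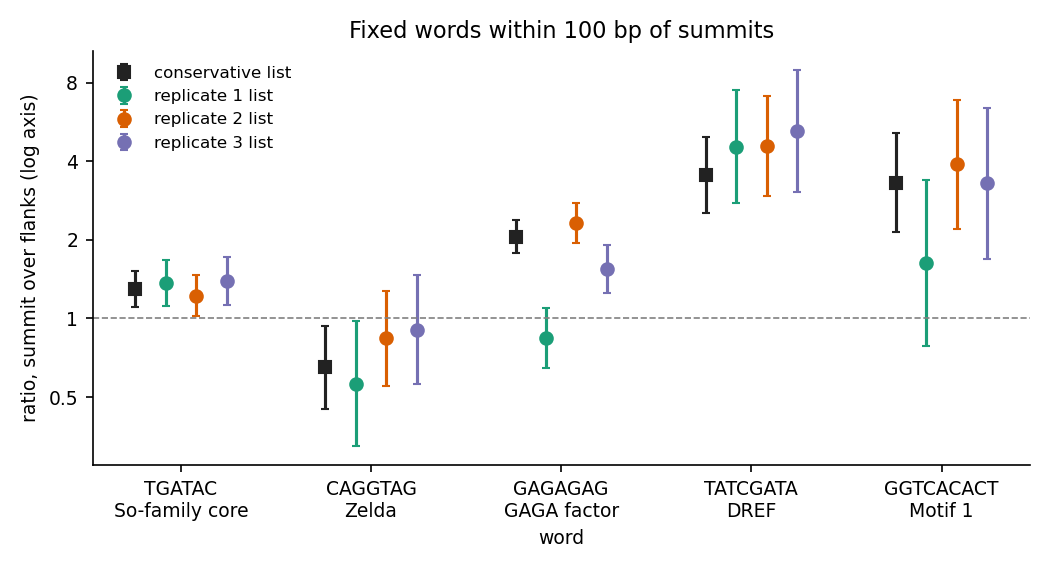
Ratio of the share of summits with each fixed word within 100 bp to that in flanking windows, on a log axis. Squares are the conservative list and circles the lists of replicates 1, 2 and 3, with 95% intervals; for GAGAGAG the replicates lie at 0.843, 2.32 and 1.55.

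The core was more frequent at stronger peaks of the conservative list. The strongest 1085 peaks had TGATAC in 7.83% of cases (95% interval 6.38 to 9.59) and the weakest 1085 in 4.70% (3.59 to 6.13), a ratio of 1.67 (Fisher's exact p = 0.00334). In their own lists replicates 1, 2 and 3 gave ratios of 0.973, 1.06 and 1.73, so this difference was not seen in each replicate. It turned to 0.941 among peaks in all 3 lists (Fisher's exact p = 1), and among conservative-list peaks found in the lists of replicates 2 and 3, 1 and 3, or 1 and 2 the ratio was 1.29, 1.20 or 1.92, none past the threshold.

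**Figure D5:**
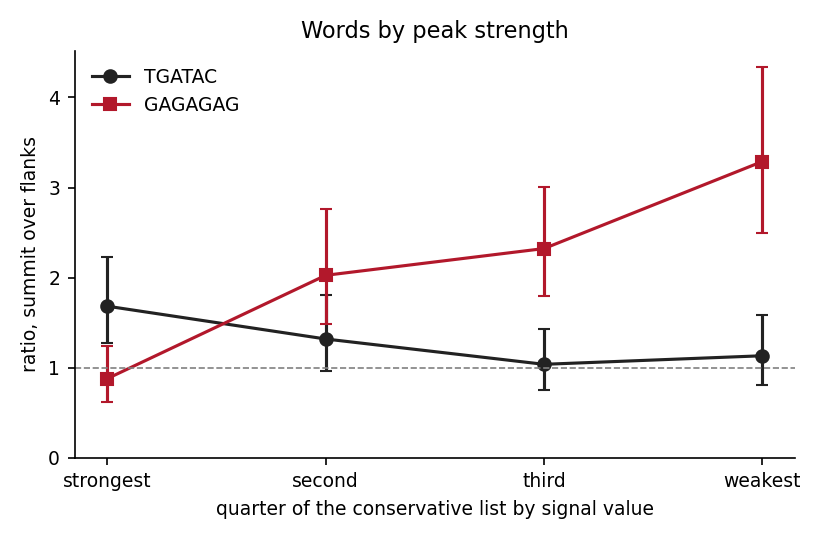
Ratio of the share of summits with TGATAC (black) and GAGAGAG (red) to that in flanking windows, by strength of the peak within the conservative list, with 95% intervals and 1085 peaks per point. TGATAC goes from 1.68 at the strongest to 1.13 at the weakest peaks and GAGAGAG, which was added after seeing the data, from 0.880 to 3.29.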

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

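These counts were looked at after the data were seen. Thresholded peaks outside the 6 assembled arms lay in data that no comparison above used, and all of them were on unplaced X scaffolds. There were 14 in replicate 1 (0.595% of its list, 95% interval 0.355 to 0.996), 5 in replicate 2 and 4 in the largest whole-series list, each above the limit of 3 that a count of 0 allows. Replicate 3 had 1 and the conservative list 3. No control list was used here to set them against.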

How the results depend on the processing

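The alternatives with peaks at the score cap and with 1 peak per cluster of overlapping peaks were chosen after seeing the data; all others were fixed before. The planned stricter IDR of 0.01 moved nothing, because every thresholded list already holds to it, and is not counted. Where a replicate is set aside, the peaks are those of the conservative list found in both other lists; that list was still made from all 3 samples. Promoter share kept its direction and call under 10 of 10 alternatives (37.97 to 56.2%). Peaks in all 3 lists numbered 674 with 50% reciprocal overlap and 3765 with the ranked lists, and peaks found in both lists of a pair numbered 1178 to 1506, as these criteria are stricter or looser by construction. The ratio of the So-family core fell to 1.05 within 200 bp of the summit, 1.03 near start sites and 1.06 for the longer consensus, and reversed to 0.783 against shuffled windows, while it was 1.52 to 1.69 with a replicate set aside. The core by strength was 1.20 to 1.92 with a replicate set aside, 1.41 at the score cap and 0.941 in all 3 lists. The X share was 16.9 to 21.2% with a replicate set aside and 20.5% in all 3 lists, above the 17.6% of length in 3 of these 4 sets. Lists past the threshold numbered 1 in all 3 lists, 1 to 2 with a replicate set aside and 7 in the largest other list, against 6; the Hedgehog, Wnt and Dpp, cell cycle and head gap lists each gained a call under 1 alternative. Ribosomal proteins kept the call under 11 of 11 alternatives, histones under 9, muscle under 7, EGFR and transfer RNA under 6 and photoreceptor specification under 2. Transfer RNA genes lost the call, at 27.9%, against lists not matched on length. Their share was 5.17% in all 3 lists, against 5.40% of matched genes, and not past the threshold. Without replicate 2 it was also 5.17%, below matched genes but not past the threshold (permutation test, adjusted p = 0.979). Signal correlation was 0.688 over thresholded peaks and 0.306 over all ranked peaks. The sets with a replicate set aside hold fewer peaks, and for every other change the cause was not tested. Of 686 pairs of a named gene and an alternative, 131 lost every peak of the gene. Depth is unknown, so what it limits cannot be given.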

Other observations

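The lists of mitochondrial ribosomal protein, proteasome and Polycomb and trithorax group genes, the *so* window, the chromosome split of the word search, the base composition test of the whole difference, the strength comparison of GAGAGAG, the choice-of-list test, the matching of repeat words on GC and the merging of overlapping peaks were chosen after the results were seen. The tests of base composition as a cause and of the So-family core, and the bound for repeats, were written before their results were seen. The design holds 1 group, so no biological explanation was tested by a comparison between groups, and the tests on promoters and on the So-family core below were made within that group.

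Mitochondrial ribosomal protein genes held peaks in 30 of 73 cases (41.1% against 18.7% of length-matched genes, permutation test, adjusted p = 0.0006 over 3 lists) and proteasome genes in 15 of 32 (46.9% against 23.25%, permutation test, adjusted p = 0.0108). Genes of the Polycomb and trithorax groups, which keep Hox genes off or on, held peaks in 14 of 22 cases (63.6% against 42.3%), at the edge of the central 95% of matched lists and not past the threshold (permutation test, adjusted p = 0.0632).

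GAGAGAG was commoner at weaker peaks. In the conservative list it lay at 11.5% of the weakest 1085 summits and 4.06% of the strongest, a ratio of 2.84 (95% interval 2.04 to 3.96). In the lists of replicates 1, 2 and 3 the ratio was 1.16, 1.51 and 1.68, and the interval for replicate 1 (0.6335 to 2.12) includes 1. Of 248 8-base words tested on chromosome 2, the one with the lowest p was AGAGAGCG, and on X, 3L, 3R and 4 its ratio over flanks was 2.92 (2.24 to 3.81). Words had been scanned on all chromosomes beforehand, so this split is not independent evidence. That word shares the uneven spread over replicates (1.09, 3.86 and 2.36), whereas CACTGAGA, named after its values were seen, was above the flanks in each replicate (6.645, 3.83 and 5.48) and had a ratio of 4.67 (2.98 to 7.31) outside chromosome 2. ACAGTG, likewise, gave 2.27, 2.19 and 2.27. No factor was assigned to either.

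The GAGAGAG word was 2.795 times (95% interval 2.17 to 3.595) as frequent at summits of replicate 2 as of replicate 1. Each is 1 library, and the intervals here treat peaks as independent, although 1350 of 2340 replicate 1 peaks overlapped the list of replicate 2. They therefore describe these 2 lists. Summit windows had a median GC of 34.3% in replicate 1, 40.3% in replicate 2 and 38.8% in replicate 3. In 1849 peaks of each matched on GC the ratio was 1.69 with a lower bound of 1.26. Over 100 further draws of the matching it ranged from 1.42 to 1.92, with a lowest lower bound of 1.055. This argues against base composition as the whole of the difference between these 2 lists. A part of the difference went with composition, since every matched ratio, at most 1.92, lay below the unmatched interval. Whether composition itself or something that varies with it was the cause cannot be told apart. The prediction written beforehand gave no decision, because the interval, 1.26 to 2.25, excludes 1 but reaches below its bound of 1.5. Repeats of any kind cannot be told apart from other causes either. In GC-matched peaks CACACAC had a ratio of 1.19 (0.938 to 1.51), ATATATA 1.04, the median of the 3 words, and AAAAAAA 0.976, so the upper bound for CACACAC reached past the 1.5 set beforehand. Without matching CACACAC was more frequent in replicate 2 (1.97) and the AT-only words rarer, which base composition alone could give, so this decides nothing.

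For ribosomal protein genes the excess was present in each of the 3 replicates' own lists, where the highest adjusted p was 0.0021 (permutation test). The rule for this test was written after the results were seen, and the lists come from the same 3 samples as the conservative list. It therefore describes these lists and is not independent evidence against the choice of peak list. The excess at mitochondrial ribosomal protein genes, 41.1%, and at proteasome genes is consistent with frequent peaks at constitutively active promoters of any kind, which stays open as a hypothesis. Binding through the So-family core cannot be told apart from its absence: TGATAC had a ratio of 1 over the flanks at 97 summits of these genes, with an interval of 0.3515 to 2.845. The DREF word TATCGATA lay at 18.6% of those summits, against 2.17% in the whole conservative list. The 2 sets differ in location: 52 of 66 of these genes had their strongest summit within 500 bp of a start site, while 45.8% of all summits lay at promoters. The word was not compared among promoter summits alone.

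The cluster of 25 peaks around *so* lay in a window of 115.5 kb, and the highest count in 2000 random windows was 23. Some of these peaks overlap each other. Merged, they made 20 clusters, at percentile 99.9 of random windows, whose highest count was 22. The density of genes is argued against, because the count of clusters was at percentile 100 among 489 windows with a like number of start sites, whose median was 5. Extra copies of the region in the transgene may contribute: weaker ranked peaks outside the conservative list had a median signal value of 15.4, 16.9 and 14.2 in replicates 1, 2 and 3, against 9.60, 11.35 and 9.67 in random windows, and the lowest of the 3 percentiles among those windows was 99.89. Real binding near *so* could raise these weaker peaks too, and the extent of the transgene is not given in the sources used here.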
